A study of Mus musculus with 24 samples.

How the data were processed

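RNA was sequenced from 24 libraries of a mouse pancreatic cancer organoid line, 3 in each of 8 groups given by 4 treatments (vehicle, 8 Gy of radiation, 1 µM FAK inhibitor, both) and 2 times (24 h and 48 h after radiation). The submitters' processing notes name bcl2fastq, STAR 2.0.4b, Subread featureCounts 1.45 and the build GRCm38, tools that demultiplex, align and count reads. They state no annotation release and no strand setting. Per the labels, libraries were made with a SMARTer kit.

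The deposited files hold, for each gene, raw counts, CPM and RPKM, with columns named in the file headers. Only the deposited counts entered the tests. The deposited CPM and deposited RPKM were recomputed from the counts when the units were checked, and were not used further. The files hold 41388 genes, of which 97.3% carry a symbol, and 99.9% of those identified in the mouse GENCODE release at hand overlap its position for the gene. Per library, 0.142% to 0.183% of the counts fall on genes with no symbol. Totals, in M (mega), run from 18.99 M to 60.2 M counts, median 38.1 M, so that 3 counts, the upper limit for a gene with none, equal 0.0498 to 0.158 CPM.

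Genes were kept by edgeR's filterByExpr over the 8 groups, which left 23353 and removed 18035. Libraries were scaled by TMM, and a model with one term per group was fitted to all 24 with edgeR 4.0.16 (glmQLFit, robust) in R 4.3.3. The common biological coefficient of variation was 19.8%, with 16 residual and a median of 14 prior degrees of freedom. Comparisons, made before the data were examined, were RT, FAKi and RT+FAKi against vehicle, RT+FAKi against each single treatment, and the interaction of RT and FAKi, each at 24 h and 48 h. Further comparisons were the difference of the RT effect and of the FAKi effect between times, and vehicle at 48 h against 24 h. Adjusted p is Benjamini and Hochberg's over all genes tested, with a threshold of 0.05.

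Also fixed before the data were examined were 46 gene lists, written from general knowledge, the rule for naming genes, and the alternatives. Lists with at least 5 members tested were compared with all other genes by camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and adjusted over the lists of a comparison. A list counts as called at an adjusted p below 0.05. Counts "adjusted over the list alone" repeat the adjustment within the list.

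Named genes are the 8 highest and 8 lowest protein-coding genes among those passing in the comparisons of RT and FAKi with vehicle and of RT+FAKi with RT, and the 5 highest and 5 lowest in the others. These need an average log2 CPM of at least 3 and, in comparisons of 3 against 3 libraries, CPM values that do not overlap between the groups. The interactions and the differences between times had no rule on overlap. Up to 4 members with the smallest p of each list called, and a panel of 24 genes fixed in advance, are named too. Genes outside the rule, Col1a1 and the other markers of macrophages and fibroblasts whose highest level is given, were chosen after the values were seen. Members of a list of FOXO targets, drawn up after the main results, are named outside the rule too. Gm10800, Gm10801 and Gm10722 are annotated as protein-coding and met the rule.

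Alternatives were DESeq2 1.42.0, RLE factors, library size as the only scaling, no filter and a stricter filter (CPM above 1 in 3 libraries and a mean count of 20), the replicate number as a replicate block, overall and within time, 1 surrogate variable from sva 3.50.0, limma voom with quality weights, fits to fewer samples, and leaving out each library in turn. For lists they were an estimated correlation, fry, the replicate block and library size. Other splits of the samples were tested too. On simulated data with known changes, made for RT against vehicle at 24 h, the pipeline found 34.3%, 67.2% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold. Of its 138 calls 5 were false, and it made 1 call in a comparison without change and called 0 of 45 unchanged lists. Simulated genes were drawn independently and those lists at random, so list calls where members vary together were not tested. The changes were few (67, 67 and 66 genes), of random direction, and among genes with an average log2 CPM above 0. Recovery of genes with fewer counts was therefore not tested. Nor were false calls under large or unbalanced changes, and real comparisons called up to 10957 genes.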

Results

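RNA was sequenced from KPOG, a 3D organoid line grown from pancreatic tumours of female KPC-OG mice, whose tumour cells carry activated Kras, floxed p53, ovalbumin and green fluorescent protein. Organoids received vehicle (DMSO), 8 Gy of radiation (RT), 1 µM of an inhibitor of the focal adhesion kinase FAK (FAKi), or both (RT+FAKi), and RNA was taken 24 h or 48 h after radiation. FAKi was added a day after plating, 2 h before radiation. Each of the 8 groups held 3 libraries, 24 in all. Total counts in M (mega) were 25.6, 22.1 and 21.8 in vehicle at 24 h and 42.7, 48.4 and 43.0 M in vehicle at 48 h. They were 31.8, 41.8 and 60.2 M in RT at 24 h and 29.9, 50.8 and 50.5 M in RT at 48 h. They were 27.0, 18.99 and 38.6 M in FAKi at 24 h and 37.7, 36.8 and 27.3 M in FAKi at 48 h. They were 43.2, 32.6 and 44.9 M in RT+FAKi at 24 h and 41.5, 23.2 and 43.7 M in RT+FAKi at 48 h. At these depths a gene with no count in a library can lie at up to 0.0498 to 0.158 CPM, a limit from 3 counts that covers counting error only.

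Of 41388 genes, 23353 were tested. Changes are log2 fold changes ± standard error from edgeR's quasi-likelihood test, and levels are CPM after scaling, as mean ± SD of n = 3 libraries, with the treated or later group first. Gene lists were tested with limma's camera at a preset correlation, and a second adjusted p is printed where the call is lost with an estimated correlation. Some lists share members, so their results are not separate. The NF-kB list and the list of secreted factors linked to senescence share 10 tested genes. The type I interferon list and the list of cytosolic nucleic acid sensors share 5. In comparisons of 3 against 3 libraries, genes named for the size of their change have CPM values that do not overlap, which chance alone gives in 10% of genes. For the interactions and the differences between times no rule on overlap applied. The labels do not say that replicates were separate cultures, so every p-value measures only the spread between libraries, which can be technical. The kit amplifies full-length cDNA and no strand setting is stated, so overlapping and antisense genes, and pseudogenes beside their parent genes, are uncertain.

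Libraries separated by treatment. The first principal component held 25.8% of the variance and placed the 6 RT+FAKi libraries at 64.9 to 108.3 and the 6 vehicle libraries at -75.0 to -52.2. The second component, 11.6%, placed RT at 48 h highest, at 73.7 to 78.8. RT replicate 3 at 24 h stood apart from its group: it lay at 20.8 on the first component against -29.1 and -24.3, had the largest total, and had 1.80% of its counts in pseudogenes against 3.27% and 2.91%. FAKi replicate 1 at 48 h had 1.76% of its counts in Gm42418, a locus over ribosomal RNA, against 0.607% and 0.772% in its group. Transcripts of mitochondrial protein genes took 0.535% to 0.638% of the counts in vehicle and 1.23% to 1.94% in RT+FAKi; the genes behind this share rose with FAKi at 48 h, mt-Cytb by 1.21 ± 0.12.

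Radiation alone was compared with vehicle to find what 8 Gy does to the tumour cells at 24 h. Serpinb2, an inhibitor of plasminogen activators, rose by 2.07 ± 0.12 (56.6 ± 10 against 13.5 ± 0.725 CPM, adjusted p = 1.29e-12). Mmp13, a collagenase, rose by 1.89 ± 0.14, and Psca, a surface antigen of pancreatic cancer cells, by 1.97 ± 0.15. Krt14, a basal keratin, rose by 1.11 ± 0.08 (336 ± 17.6 against 156 ± 4.80 CPM) and Krt6a by 1.36 ± 0.13. Ccl20, which draws dendritic cells and lymphocytes, rose by 1.68 ± 0.15, and Cxcl1, which draws neutrophils, by 0.95 ± 0.10. Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 1.06 ± 0.12 (adjusted p = 2.34e-07). Among the lowest, Hist1h1b, a linker histone, fell by 1.32 ± 0.19 (38.3 ± 5.26 against 95.3 ± 16.9 CPM), and Mvd and Mvk of the mevalonate pathway fell by 0.79 ± 0.08 and 0.80 ± 0.08.

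Lists at 24 h after radiation moved as follows. In the NF-kB inflammatory list, 20 of 41 genes rose, 0 fell and 21 did not pass (25 and 1 adjusted over the list alone), with a median of 0.66 (camera, adjusted p = 2.52e-12). Among type I interferon-stimulated genes, 17 of 48 genes rose, 0 fell and 31 did not pass (23 and 0 adjusted over the list alone), median 0.66 (adjusted p = 2.91e-07); Ddx58, an RNA sensor, rose by 0.76 ± 0.15. Among genes of basal-type pancreatic cancer, 12 of 31 genes rose, 0 fell and 19 did not pass (14 and 0 adjusted over the list alone), median 0.57 (adjusted p = 1.36e-07). Among secreted factors linked to senescence, 16 of 39 genes rose, 1 fell and 22 did not pass (17 and 1 adjusted over the list alone), median 0.41 (adjusted p = 3.44e-08); Plat, a plasminogen activator, rose by 1.28 ± 0.08. For cholesterol synthesis, 0 of 25 genes rose, 8 fell and 17 did not pass (0 and 10 adjusted over the list alone), median -0.21 (adjusted p = 0.00011, adjusted p = 0.142 with an estimated correlation). Ribosomal protein genes had a median of 0.39 and a test upward (adjusted p = 0.00343, adjusted p = 0.692 with an estimated correlation), yet the only member past the threshold, Rpl8, fell by 0.39 ± 0.08. Among ligands read by immune cells, 4 of 22 genes rose, 0 fell and 18 did not pass (4 and 0 adjusted over the list alone), median 0.70 (adjusted p = 0.00741, adjusted p = 0.0607 with an estimated correlation), with Pvr, a ligand of TIGIT, up by 0.65 ± 0.09. In the list of p53 targets, 6 of 35 genes rose, 1 fell and 28 did not pass (6 and 1 adjusted over the list alone), median 0.06 (adjusted p = 0.205).

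By edgeR, 3527 genes changed at 24 h after radiation, 1880 higher and 1647 lower, and 546 of the lower were pseudogenes against 34 of the higher. Pseudogenes took 1.80% to 3.27% of the counts in RT and 4.22% to 4.74% in vehicle at 24 h. In every other comparison of a treatment with vehicle or with a single treatment, more pseudogenes fell than rose. With FAKi at 24 h 409 fell and 49 rose, and with RT+FAKi against vehicle at 48 h 1001 fell and 129 rose. Camera called 22 of 46 lists, 6 of them with an estimated correlation. Without vehicle replicate 2 the count of changed genes was 2263, with 1 surrogate variable 1684, and with only the groups compared 1145. The higher share, 53.3%, was 44.0% with library size as the only scaling.

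At 48 h after radiation, Cxcl10, a chemokine for T cells, rose by 4.38 ± 0.22 (23.5 ± 1.37 against 1.13 ± 0.0704 CPM, adjusted p = 6.52e-16), and Ccl5 by 4.52 ± 0.34. Csf2, which encodes GM-CSF, rose by 3.72 ± 0.16 (45.5 ± 5.59 against 3.46 ± 0.650 CPM), Cxcl2 by 3.24 ± 0.15 and Mmp13 by 3.84 ± 0.14. Cd74, the invariant chain of MHC class II, rose by 3.72 ± 0.22 (12.8 ± 1.34 against 0.971 ± 0.244 CPM). Krt14 rose by 2.25 ± 0.08 and Krt16, a stress keratin, by 3.34 ± 0.23. Among the genes that fell were members of the hypoxia list: Bnip3, a mitophagy receptor, fell by 4.69 ± 0.15 (9.60 ± 1.19 against 248 ± 7.64 CPM), and Slc16a3, a lactate exporter, by 4.54 ± 0.14 (6.68 ± 0.921 against 156 ± 11.2 CPM). In vehicle, Bnip3 and Slc16a3 rose from 24 h to 48 h, by 5.21 ± 0.16 and 4.60 ± 0.14.

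Among type I interferon-stimulated genes at 48 h, 37 of 48 genes rose, 0 fell and 11 did not pass (40 and 0 adjusted over the list alone), median 1.68 (camera, adjusted p = 8.44e-20); Isg15 and Ifit1 both rose by 3.58, and Irf7, a transcription factor of the response, by 2.38 ± 0.18. For cytosolic nucleic acid sensors, 9 of 20 genes rose, 3 fell and 8 did not pass (9 and 4 adjusted over the list alone), median 0.23 (adjusted p = 0.0118), with Ifih1 up by 1.27 ± 0.17. In MHC class I presentation, 11 of 24 genes rose, 2 fell and 11 did not pass (12 and 2 adjusted over the list alone), median 0.52 (adjusted p = 0.00117, adjusted p = 0.0727 with an estimated correlation); Tapbp, which loads peptides, rose by 1.04 ± 0.09. In the NF-kB list, 35 of 41 genes rose, 2 fell and 4 did not pass (37 and 2 adjusted over the list alone), median 1.65 (adjusted p = 3.64e-27). For immediate early genes, 17 of 24 genes rose, 0 fell and 7 did not pass (18 and 0 adjusted over the list alone), median 1.01 (adjusted p = 4.92e-12), with Atf3 up by 1.89 ± 0.11. For mesenchymal genes, 8 of 21 genes rose, 0 fell and 13 did not pass (9 and 1 adjusted over the list alone), median 0.70 (adjusted p = 0.00112); Vim, an intermediate filament, rose by 2.60 ± 0.17. For ERK feedback genes, 15 of 27 genes rose, 2 fell and 10 did not pass (15 and 2 adjusted over the list alone), median 0.40 (adjusted p = 1.06e-05, adjusted p = 0.116 with an estimated correlation), with Ereg, an EGF receptor ligand, up by 1.83 ± 0.12. For STAT3 targets, 10 of 24 genes rose, 4 fell and 10 did not pass (11 and 4 adjusted over the list alone), median 0.56 (adjusted p = 0.0461, adjusted p = 0.138 with an estimated correlation), with Pim1 up by 1.32 ± 0.10.

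The following lists tested lower 48 h after radiation. For hypoxia and glycolysis, 2 of 36 genes rose, 28 fell and 6 did not pass (2 and 29 adjusted over the list alone), median -0.97 (camera, adjusted p = 1.67e-21). From 24 h to 48 h the median of this list moved by 1.34 in vehicle and by 0 with RT. For cholesterol synthesis, 0 of 25 genes rose, 21 fell and 4 did not pass (0 and 22 adjusted over the list alone), median -0.94 (adjusted p = 1.79e-22); Acat2 fell by 1.63 ± 0.10 (238 ± 12.9 against 735 ± 29.7 CPM). For fatty acid synthesis, 1 of 20 genes rose, 14 fell and 5 did not pass (1 and 14 adjusted over the list alone), median -0.52 (adjusted p = 8.07e-10), and Scd2, a desaturase, fell by 1.58 ± 0.11. For nuclear respiratory chain subunits, 0 of 55 genes rose, 37 fell and 18 did not pass (0 and 42 adjusted over the list alone), median -0.34 (adjusted p = 4.38e-13, adjusted p = 0.104 with an estimated correlation). For DNA replication genes, 0 of 50 genes rose, 28 fell and 22 did not pass (0 and 31 adjusted over the list alone), median -0.32 (adjusted p = 9.18e-12). Library composition differed between RT and vehicle at 48 h: mitochondrial ribosomal RNA took 0.748% to 0.973% and 0.465% to 0.478% of the counts. By edgeR, 6215 genes changed, 3596 higher and 2619 lower, so 57.9% were higher, against 70.0% with library size as the only scaling and 49.4% with no filter on low counts. Camera called 31 lists, 14 with an estimated correlation.

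The effect of radiation was tested for a difference between 48 h and 24 h. The difference was 3.14 ± 0.31 for Cxcl10 (adjusted p = 3.17e-08), 2.90 ± 0.45 for Isg15 and 2.16 ± 0.22 for Csf2. Tnf, a cytokine of the NF-kB response, differed by 2.10 ± 0.28, and Slpi, a protease inhibitor, by 2.35 ± 0.27. Among protein-coding genes with an average log2 CPM of at least 3, Selenbp1, a selenium-binding oxidase, had the lowest difference, -5.21 ± 0.23, followed by Bnip3 at -4.61 ± 0.20. In the NF-kB list, 25 of 41 were positive, 1 negative and 15 did not pass (28 and 1 adjusted over the list alone), median 0.99 (camera, adjusted p = 9.11e-21). For type I interferon genes, 21 of 48 were positive, 1 negative and 26 did not pass (25 and 1 adjusted over the list alone), median 0.90 (adjusted p = 1.12e-11). For hypoxia and glycolysis, 0 of 36 were positive, 27 negative and 9 did not pass (1 and 29 adjusted over the list alone), median -1.34 (adjusted p = 3.97e-39). The edgeR test called 1743 genes, 876 positive and 867 negative. The positive share, 50.3%, was 75.8% with library size as the only scaling, 40.4% with DESeq2, 40.6% with RLE scaling, 29.8% with no filter on low counts, and 23.9% to 37.6% with a library left out. Which sign leads therefore rests on the processing.

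FAKi alone was compared with vehicle to find what the inhibitor does to tumour cells without stroma at 24 h. Vcam1, which binds leukocyte integrins, rose by 4.51 ± 0.18 (78.2 ± 6.55 against 3.44 ± 0.969 CPM, adjusted p = 3.64e-15). Acta1, a muscle actin driven by SRF, rose by 3.97 ± 0.14 (78.3 ± 3.97 against 4.99 ± 1.12 CPM). Ccl2, which draws monocytes, rose by 3.77 ± 0.18, Cxcl2 by 3.37 ± 0.16 and Lcn2, an iron-binding acute phase protein, by 3.16 ± 0.18. Aqp5, a water channel of secretory ducts, fell by 3.10 ± 0.11 (35.8 ± 4.20 against 308 ± 9.74 CPM). Krt4, a mucosal keratin, fell by 2.51 ± 0.09 (474 ± 7.50 against 2708 ± 60.4 CPM, adjusted p = 1.81e-19). Ascl2, a stem cell transcription factor, fell by 1.98 ± 0.20 and Ccnd2, a G1 cyclin, by 1.97 ± 0.11.

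With FAKi at 24 h, the following lists tested lower. Among MYC targets and ribosome biogenesis genes, 0 of 38 genes rose, 34 fell and 4 did not pass (0 and 37 adjusted over the list alone), median -0.72 (camera, adjusted p = 4.36e-25); Ncl, a nucleolar protein, fell by 0.99 ± 0.07 (1298 ± 66.0 against 2572 ± 128 CPM). For mitosis, 0 of 50 genes rose, 42 fell and 8 did not pass (0 and 45 adjusted over the list alone), median -0.48 (adjusted p = 2.33e-21), with Aurka down by 0.94 ± 0.08. For replication, 0 of 50 genes rose, 38 fell and 12 did not pass (0 and 40 adjusted over the list alone), median -0.49 (adjusted p = 3.82e-19), with Rrm2 down by 1.13 ± 0.08. For targets of ATF4, 1 of 30 genes rose, 17 fell and 12 did not pass (1 and 19 adjusted over the list alone), median -0.64 (adjusted p = 2.81e-12), with Asns, which makes asparagine, down by 1.18 ± 0.08. For NRF2 targets, 1 of 30 genes rose, 15 fell and 14 did not pass (1 and 16 adjusted over the list alone), median -0.35 (adjusted p = 1.01e-05, adjusted p = 0.0547 with an estimated correlation). For cholesterol synthesis, 0 of 25 genes rose, 20 fell and 5 did not pass (0 and 21 adjusted over the list alone), median -0.54 (adjusted p = 8.61e-15).

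The following lists tested higher with FAKi at 24 h. In the NF-kB list, 32 of 41 genes rose, 2 fell and 7 did not pass (34 and 2 adjusted over the list alone), median 1.46 (camera, adjusted p = 1.06e-22); Csf1, a macrophage growth factor, rose by 2.17 ± 0.12. Among SRF and MRTF targets, 25 of 33 genes rose, 0 fell and 8 did not pass (25 and 0 adjusted over the list alone), median 0.74 (adjusted p = 2.21e-15), with Cald1, an actin-binding protein, up by 2.54 ± 0.11. For interferon-gamma-inducible GTPases, 11 of 19 genes rose, 0 fell and 8 did not pass (12 and 0 adjusted over the list alone), median 1.30 (adjusted p = 3.39e-07), with Irgm1 up by 1.28 ± 0.11. For core apoptosis genes, 13 of 31 genes rose, 2 fell and 16 did not pass (15 and 5 adjusted over the list alone), median 0.44 (adjusted p = 0.00109); Pmaip1, a killer of the BCL2 family, rose by 2.24 ± 0.11 (142 ± 11.2 against 29.9 ± 5.38 CPM). For focal adhesion and integrin genes, 21 of 38 genes rose, 2 fell and 15 did not pass (23 and 2 adjusted over the list alone), median 0.47 (adjusted p = 1.58e-06, adjusted p = 0.154 with an estimated correlation), with Itgb6 up by 1.66 ± 0.08. For matrix genes, 15 of 43 genes rose, 2 fell and 26 did not pass (15 and 2 adjusted over the list alone), median 0.45 (adjusted p = 0.000373, adjusted p = 0.138 with an estimated correlation); Fn1, fibronectin, rose by 2.47 ± 0.22. For lysosome and autophagy genes, 19 of 34 genes rose, 0 fell and 15 did not pass (20 and 2 adjusted over the list alone), median 0.32 (adjusted p = 2.49e-05, adjusted p = 0.0608 with an estimated correlation), with Lamp2 up by 0.96 ± 0.09. For epithelial and ductal genes, 12 of 29 genes rose, 2 fell and 15 did not pass (13 and 2 adjusted over the list alone), median 0.15 (adjusted p = 0.0267, adjusted p = 0.349 with an estimated correlation). By edgeR, 5279 genes changed, 2548 higher and 2731 lower. The higher share was 48.3%, against 63.9% with library size as the only scaling. Camera called 29 lists, 12 with an estimated correlation.

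**Figure D1:**
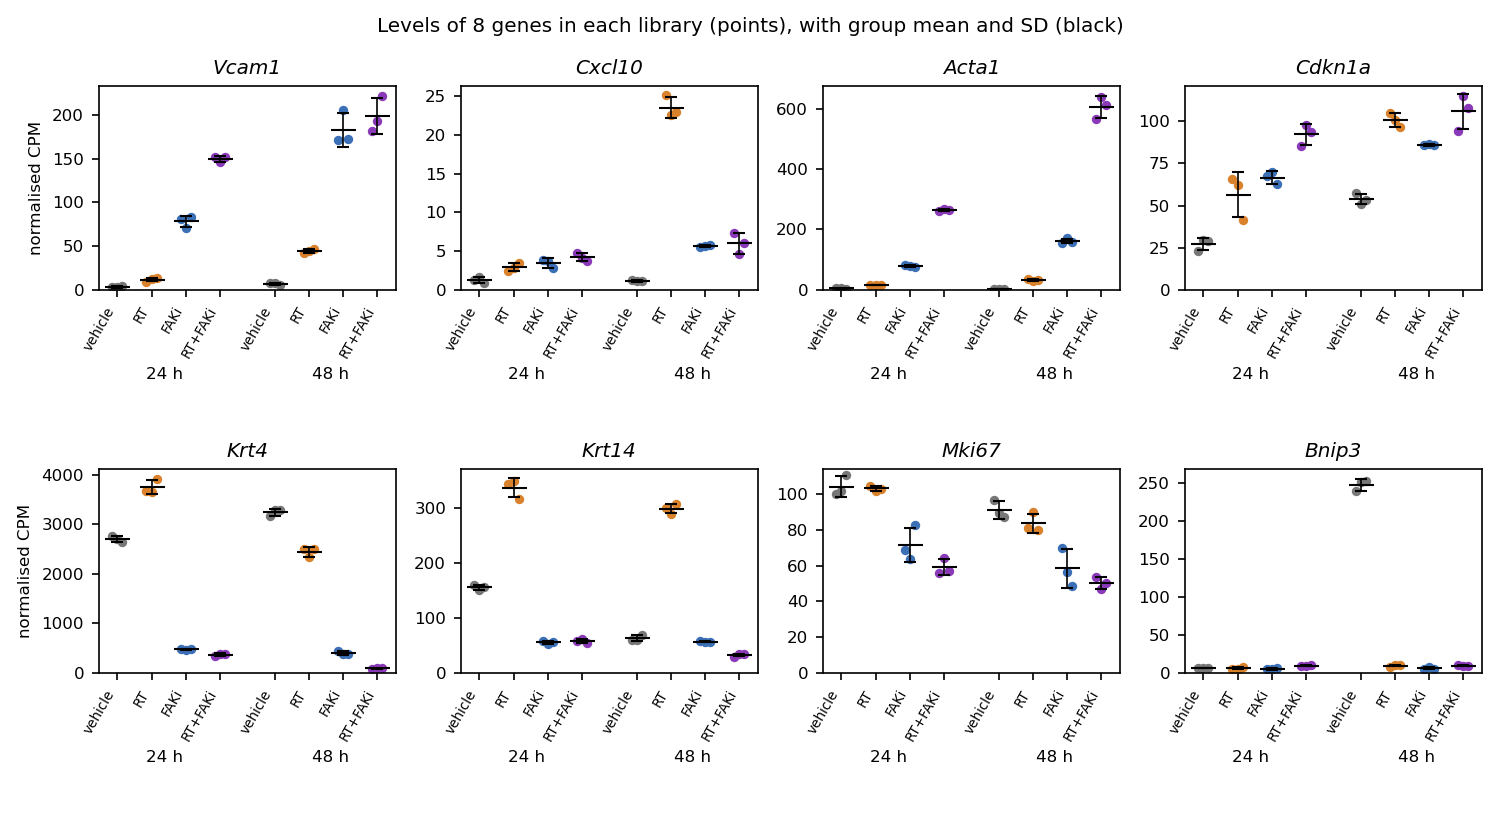
Normalised CPM of 8 genes (vertical axes, linear from 0) in each library (points) of the 4 treatments at 24 h and 48 h, with the mean and SD of the 3 libraries per group in black. Acta1 reached 606 CPM in RT+FAKi at 48 h against 2.86 CPM in vehicle, and Krt4 lay at 91.1 CPM against 3245 CPM.

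At 48 h of FAKi many of the same genes differed from vehicle. Acta1 rose by 5.81 ± 0.15 (161 ± 7.69 against 2.86 ± 0.857 CPM, adjusted p = 2.86e-21), Vcam1 by 4.78 ± 0.17 (183 ± 19.2 against 6.64 ± 1.57 CPM) and Lcn2 by 4.45 ± 0.16 (144 ± 21.6 against 6.57 ± 0.595 CPM). Ctla2a, a cysteine protease inhibitor, rose by 4.05 ± 0.17, Lce1h, a protein of the cornified envelope, by 4.55 ± 0.26 and Cd74 by 4.41 ± 0.23. Krt4 fell by 3.01 ± 0.09 (402 ± 32.2 against 3245 ± 69.9 CPM) and Aqp5 by 3.00 ± 0.11. Adm, a vasodilator peptide induced by low oxygen, fell by 4.41 ± 0.19 and Pdk1, which holds pyruvate back from mitochondria, fell by 3.66 ± 0.31. Ptk2b, the kinase PYK2 related to FAK, rose by 0.72 ± 0.13 (adjusted p = 5.95e-05).

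Among SRF and MRTF targets at 48 h of FAKi, 28 of 33 genes rose, 0 fell and 5 did not pass (28 and 0 adjusted over the list alone), median 1.06 (camera, adjusted p = 2.32e-19). In TGF-beta response genes, 16 of 29 genes rose, 1 fell and 12 did not pass (19 and 1 adjusted over the list alone), median 0.46 (adjusted p = 1.57e-06), with Tgif1 up by 1.21 ± 0.08. Among YAP and TEAD targets, 14 of 29 genes rose, 2 fell and 13 did not pass (15 and 2 adjusted over the list alone), median 0.37 (adjusted p = 1.43e-05); Edn1, endothelin, rose by 3.55 ± 0.14, while Ccn2 did not pass (0.24 ± 0.09, adjusted p = 0.0542). All 13 mitochondrially encoded genes rose (13 adjusted over the list alone), median 0.97 (adjusted p = 1.48e-07). Library composition differed between these groups: mitochondrial ribosomal RNA took 0.898% to 1.24% of the counts in FAKi and 0.465% to 0.478% in vehicle. For ligands read by immune cells, 10 of 22 genes rose, 1 fell and 11 did not pass (11 and 1 adjusted over the list alone), median 0.78 (adjusted p = 0.00134), with Cd40 up by 5.49 ± 0.65 (4.73 ± 0.518 against 0.104 ± 0.142 CPM). For the unfolded protein response, 1 of 24 genes rose, 16 fell and 7 did not pass (1 and 16 adjusted over the list alone), median -0.35 (adjusted p = 6.03e-06, adjusted p = 0.115 with an estimated correlation), with Herpud1 down by 0.92 ± 0.09. For DNA repair, 5 of 44 genes rose, 23 fell and 16 did not pass (5 and 24 adjusted over the list alone), median -0.35 (adjusted p = 2.44e-05), with Rad51 down by 0.62 ± 0.10. For hypoxia and glycolysis, 0 of 36 genes rose, 30 fell and 6 did not pass (0 and 34 adjusted over the list alone), median -1.40 (adjusted p = 2.88e-27). From 24 h to 48 h the median of this list moved by 1.34 in vehicle and by 0.13 with FAKi. By edgeR, 6550 genes changed, 3529 higher and 3021 lower, and camera called 32 lists, 23 with an estimated correlation. The higher share, 53.9%, was 65.1% with library size as the only scaling and 48.5% with DESeq2.

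The effect of FAKi differed between 48 h and 24 h for 569 genes by edgeR, 354 positive and 215 negative. Cnn1, a smooth muscle calponin, differed by 1.99 ± 0.32, Acta1 by 1.84 ± 0.20 and Wfdc18, a secreted protease inhibitor, by 1.76 ± 0.26. Among protein-coding genes with an average log2 CPM of at least 3, the most negative was Bnip3 at -4.99 ± 0.21 (adjusted p = 7.48e-17). For hypoxia and glycolysis, 0 of 36 were positive, 26 negative and 10 did not pass (0 and 30 adjusted over the list alone), median -1.14 (camera, adjusted p = 5.82e-48). For ATF4 targets, 0 of 30 were positive, 9 negative and 21 did not pass (0 and 14 adjusted over the list alone), median -0.35 (adjusted p = 1.66e-11). The count was 335 without FAKi replicate 3 at 24 h and 1012 with voom. The share of positive calls, 62.2%, was 44.1% with DESeq2 and 45.7% with RLE scaling.

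RT+FAKi was compared with RT to find what FAKi adds to radiation. At 24 h, Acta1 rose by 4.14 ± 0.14 (264 ± 4.01 against 14.9 ± 0.516 CPM, adjusted p = 1.29e-18) and Vcam1 by 3.69 ± 0.16 (150.2 ± 3.38 against 11.6 ± 1.92 CPM). Slfn2, an interferon-inducible regulator of quiescence, rose by 2.87 ± 0.13, Casp4, the caspase that senses lipopolysaccharide, by 2.52 ± 0.21 and Cd74 by 2.60 ± 0.21. Among keratins named for their size of change, Krt4 fell by 3.36 ± 0.09 (367 ± 24.9 against 3753 ± 145 CPM), Krt14 fell by 2.55 ± 0.08 (57.5 ± 3.25 against 336 ± 17.6 CPM) and Krt79 fell by 2.56 ± 0.15. Tff1, a mucosal repair peptide, fell by 2.49 ± 0.27 and Cnfn, a cornified envelope protein, by 2.92 ± 0.31. Cdkn1a rose by 0.71 ± 0.12 and Mki67, a proliferation marker, fell by 0.80 ± 0.10.

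For MYC targets at 24 h, 0 of 38 genes rose, 36 fell and 2 did not pass (0 and 37 adjusted over the list alone), median -0.92 (camera, adjusted p = 4.93e-30). Library composition differed between these groups. Genes below 45% GC took 20.9% to 22.2% of the counts in RT+FAKi and 19.7% to 20.8% in RT, and mitochondrial ribosomal RNA 1.32% to 1.53% and 0.852% to 1.00%. In the basal-type list, 0 of 31 genes rose, 18 fell and 13 did not pass (1 and 20 adjusted over the list alone), median -0.71 (adjusted p = 2.17e-08), and in the classical-type list 2 of 33 genes rose, 10 fell and 21 did not pass (2 and 11 adjusted over the list alone), median -0.32 (adjusted p = 0.00654). For replication-dependent histones, 0 of 39 genes rose, 16 fell and 23 did not pass (0 and 16 adjusted over the list alone), median -1.23 (adjusted p = 1.47e-08, adjusted p = 0.111 with an estimated correlation), with Hist1h1b down by 2.49 ± 0.20. For ERK feedback genes, 2 of 27 genes rose, 11 fell and 14 did not pass (2 and 12 adjusted over the list alone), median -0.24 (adjusted p = 0.000953, adjusted p = 0.263 with an estimated correlation), with Fosl1, an AP-1 factor, down by 1.74 ± 0.14. Among WNT targets, 8 of 21 genes rose, 4 fell and 9 did not pass (9 and 4 adjusted over the list alone), median 0.20 (adjusted p = 0.0485, adjusted p = 0.263 with an estimated correlation), with Lgr5, a stem cell receptor, up by 0.85 ± 0.14. For the NF-kB list, 26 of 41 genes rose, 2 fell and 13 did not pass (29 and 2 adjusted over the list alone), median 0.81 (adjusted p = 7.55e-13); Il33, an alarmin, was one of its members that fell, by 1.79 ± 0.12. By edgeR, 5699 genes changed, 2307 higher and 3392 lower. The higher share was 40.5%, against 68.3% with library size as the only scaling, and voom called 8601 genes. Camera called 28 lists, 14 with an estimated correlation.

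At 48 h, against RT, Cnn1 rose by 4.48 ± 0.21 (38.5 ± 4.31 against 1.72 ± 0.123 CPM, adjusted p = 1.42e-16), Acta1 by 4.26 ± 0.13 and Tnc, the matrix protein tenascin C, by 2.65 ± 0.30. Palld, an actin scaffold, rose by 2.70 ± 0.34. Gm10800, Gm10801 and Gm10722, predicted genes over satellite repeats, rose by 2.86 ± 0.42, 2.89 ± 0.26 and 2.76 ± 0.34. Krt4 fell by 4.74 ± 0.09 (91.1 ± 11.5 against 2442 ± 100 CPM), Krt14 fell by 3.22 ± 0.08 and Tff1 by 4.16 ± 0.29. Prl2c2 and Prl2c3, near-identical proliferin genes that share reads, fell by 3.53 ± 0.14 and 3.38 ± 0.21. Gsta1, a glutathione transferase, fell by 3.67 ± 0.25. Cxcl10 fell by 1.97 ± 0.19 (5.99 ± 1.33 against 23.5 ± 1.37 CPM) and Isg15 by 1.51 ± 0.28.

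Every member of the ribosomal protein list fell at 48 h, with a median of -1.18 (74 of 74, and 74 adjusted over the list alone; camera, adjusted p = 4.07e-23, adjusted p = 0.231 with an estimated correlation), and so did every MYC target (38 of 38, and 38 adjusted over the list alone), median -1.04 (adjusted p = 4.07e-23). Library composition differed between the same groups: genes below 45% GC took 21.3% to 23.7% of the counts in RT+FAKi and 19.7% to 20.8% in RT, and mitochondrial ribosomal RNA 1.28% to 2.20% and 0.748% to 0.973%. In NRF2 targets, 1 of 30 genes rose, 24 fell and 5 did not pass (1 and 24 adjusted over the list alone), median -0.62 (adjusted p = 5.91e-11), with Hmox1, heme oxygenase, down by 1.53 ± 0.10. In the basal-type list, 3 of 31 genes rose, 20 fell and 8 did not pass (3 and 20 adjusted over the list alone), median -1.11 (adjusted p = 4.2e-08). For SRF and MRTF targets, 23 of 33 genes rose, 4 fell and 6 did not pass (24 and 4 adjusted over the list alone), median 0.73 (adjusted p = 4.2e-08), with Myl9, a myosin light chain, up by 4.87 ± 0.28. For matrix genes, 21 of 43 genes rose, 4 fell and 18 did not pass (21 and 4 adjusted over the list alone), median 0.78 (adjusted p = 5.21e-05, adjusted p = 0.118 with an estimated correlation); Thbs1 rose by 2.36 ± 0.21 (616 ± 44.2 against 120.3 ± 12.5 CPM). The type I interferon list had a median of -0.29 and was not called (adjusted p = 0.342). By edgeR, 8639 genes changed, 3575 higher and 5064 lower. The higher share, 41.4%, was 70.6% with library size as the only scaling. Camera called 23 lists, 9 with an estimated correlation.

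RT+FAKi was also compared with FAKi, to find what radiation adds to the inhibitor. At 24 h, Acta1 rose by 1.75 ± 0.12 (264 ± 4.01 against 78.3 ± 3.97 CPM, adjusted p = 4.96e-10), Casp4 by 1.60 ± 0.20 and Enpp2, which makes lysophosphatidic acid, by 1.65 ± 0.15. The histone genes Hist1h1b and Hist1h2ae were among the lowest. Hist1h1b fell by 2.61 ± 0.20 (6.81 ± 0.325 against 41.8 ± 6.63 CPM) and Hist1h2ae fell by 2.29 ± 0.29. For replication histones, 0 of 39 genes rose, 12 fell and 27 did not pass (0 and 12 adjusted over the list alone), median -0.72 (camera, adjusted p = 1.04e-06, adjusted p = 0.248 with an estimated correlation). For type I interferon genes, 10 of 48 genes rose, 0 fell and 38 did not pass (12 and 0 adjusted over the list alone), median 0.43 (adjusted p = 2.9e-07). For MYC targets, 0 of 38 genes rose, 19 fell and 19 did not pass (0 and 25 adjusted over the list alone), median -0.31 (adjusted p = 8.92e-13). For tuft cell markers, 4 of 11 genes rose, 0 fell and 7 did not pass (5 and 0 adjusted over the list alone), median 0.84 (adjusted p = 1.24e-05). By edgeR, 1796 genes changed, 806 higher and 990 lower, and camera called 14 lists, 3 with an estimated correlation. With library size as the only scaling 57.7% were higher, against 44.9%. The count was 1089 without RT+FAKi replicate 1, 3274 with only the groups compared and 3479 with voom.

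At 48 h against FAKi, Cnn1 rose by 2.67 ± 0.19 (adjusted p = 5.12e-12) and Acta1 by 1.91 ± 0.12 (606 ± 37.4 against 161 ± 7.69 CPM). Reg3b, an antibacterial lectin, fell by 3.42 ± 0.21 (4.71 ± 1.07 against 50.8 ± 6.16 CPM) and Krt4 fell by 2.14 ± 0.08. Among nuclear respiratory chain subunits 54 of 55 fell (55 adjusted over the list alone), median -0.77 (camera, adjusted p = 6e-28). Genes below 45% GC took 21.3% to 23.7% of the counts in RT+FAKi and 17.9% to 20.4% in FAKi, and mitochondrial ribosomal RNA 1.28% to 2.20% and 0.898% to 1.24%. Satellite-repeat loci summed to 2420 ± 1000 and 455 ± 114 CPM. For cholesterol synthesis, 0 of 25 genes rose, 22 fell and 3 did not pass (0 and 24 adjusted over the list alone), median -0.88 (adjusted p = 1.51e-17). For matrix genes, 15 of 43 genes rose, 0 fell and 28 did not pass (16 and 0 adjusted over the list alone), median 0.71 (adjusted p = 4.23e-06, adjusted p = 0.11 with an estimated correlation). Cd274, the checkpoint ligand PD-L1, rose (3.69 ± 0.498 against 1.35 ± 0.570 CPM, adjusted p = 0.0032). By edgeR, 7119 genes changed, 2550 higher and 4569 lower, and camera called 11 lists, 5 with an estimated correlation. The higher share, 35.8%, was 72.5% with library size as the only scaling and 46.9% with DESeq2. With 1 surrogate variable 3952 genes changed.

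RT+FAKi was compared with vehicle to find the joint change. At 24 h, Acta1 rose by 5.72 ± 0.15, Vcam1 by 5.45 ± 0.18 and Cd74 by 3.90 ± 0.24 (12.7 ± 0.899 against 0.862 ± 0.486 CPM), while Hist1h1b fell by 3.80 ± 0.21 and Krt4 by 2.88 ± 0.09. At 48 h, Acta1 rose by 7.72 ± 0.16 (606 ± 37.4 against 2.86 ± 0.857 CPM, adjusted p = 1.24e-23) and Cnn1 by 6.09 ± 0.23, while Krt4 fell by 5.16 ± 0.10 (91.1 ± 11.5 against 3245 ± 69.9 CPM). B2m, the light chain of MHC class I, rose by 1.84 ± 0.13 and Cd274 by 2.37 ± 0.39. In the NF-kB list at 48 h, 36 of 41 genes rose, 2 fell and 3 did not pass (36 and 2 adjusted over the list alone), median 2.43 (camera, adjusted p = 6.49e-17), and in replication, 0 of 50 genes rose, 47 fell and 3 did not pass (0 and 47 adjusted over the list alone), adjusted p = 7.36e-22. Library composition differed between these groups at 48 h. Genes below 45% GC took 21.3% to 23.7% of the counts in RT+FAKi and 17.6% to 18.4% in vehicle, and mitochondrial ribosomal RNA 1.28% to 2.20% and 0.465% to 0.478%. By edgeR, 8649 genes changed at 24 h, 4110 higher and 4539 lower, and 10957 at 48 h, 5485 higher and 5472 lower. With 1 surrogate variable the count at 24 h was 4137, beside 4164 for FAKi alone. Camera called 26 and 29 lists, 15 and 18 with an estimated correlation. The median log2 change of all genes was 0.12 at 24 h and 0.24 at 48 h, and the changes stand relative to these; with library size as the only scaling it was 0.65 at 48 h. The higher shares, 47.5% and 50.1%, were 61.8% and 73.7% with library size as the only scaling.

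**Figure D2:**
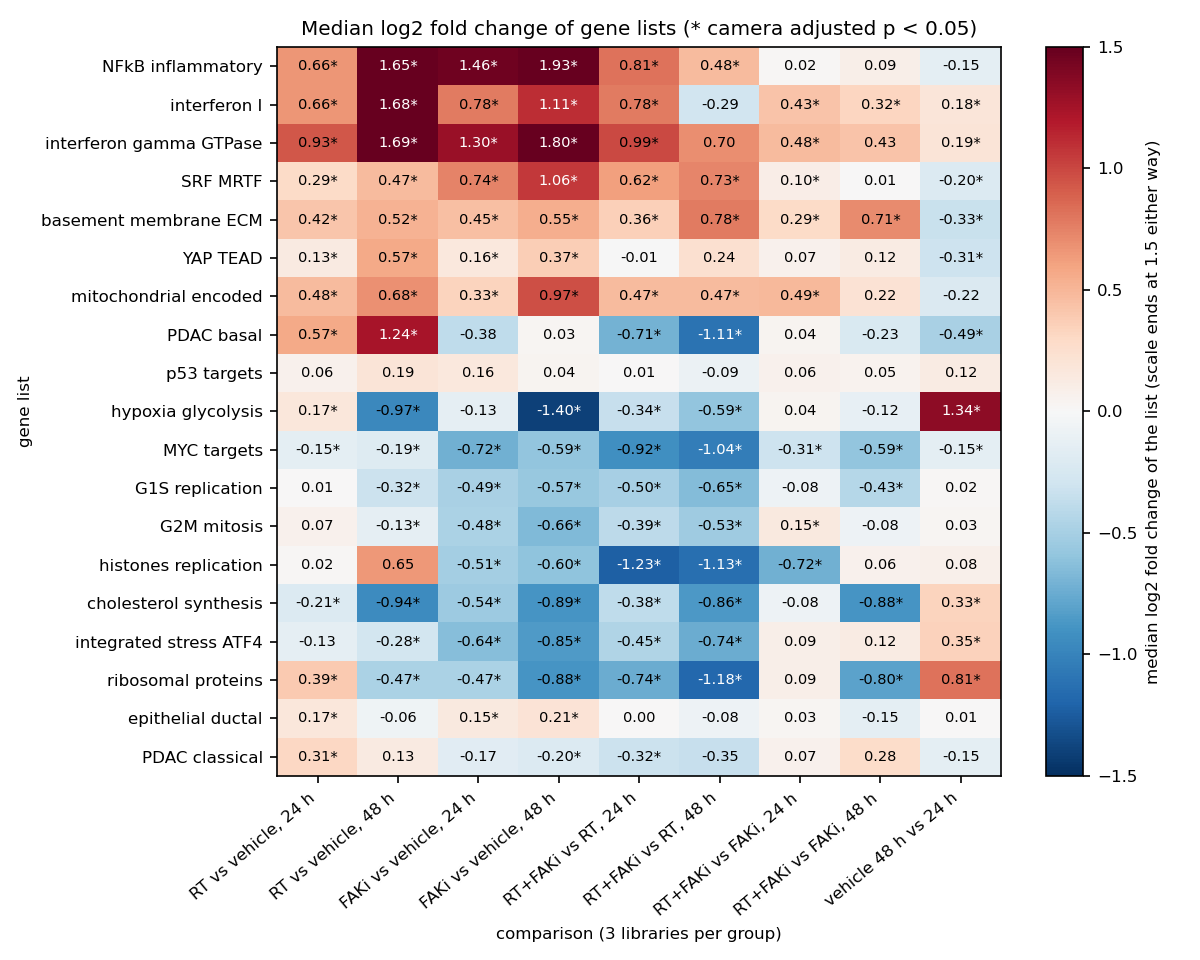
Median log2 fold change (colour and printed value) of 19 gene lists in 9 comparisons of 3 against 3 libraries, with asterisks at a camera adjusted p below 0.05. The NF-kB list lay between 0.48 and 1.93 in the 6 comparisons of RT or FAKi with vehicle and of RT+FAKi with RT, and the p53 list bore no asterisk.

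The interaction of RT and FAKi tests whether the joint change departs from the sum of the single changes on the log scale. A negative value means that the joint change lies below that sum, be it a smaller rise or a larger fall. At 24 h, Ccl2 had -2.31 ± 0.23 (adjusted p = 1.17e-06) and lay at 29.2 ± 5.43 against 46.5 ± 3.66 CPM in RT+FAKi and FAKi. Serpinb2 had -1.72 ± 0.17, Egr1, an immediate early factor, -1.93 ± 0.25, and Ascl2 1.86 ± 0.27. In the NF-kB list, 0 of 41 were positive, 9 negative and 32 did not pass (1 and 20 adjusted over the list alone), median -0.45 (camera, adjusted p = 2.47e-12), and in the basal-type list 0 of 31 were positive, 4 negative and 27 did not pass (0 and 12 adjusted over the list alone), median -0.54 (adjusted p = 7.95e-09). The edgeR test called 234 genes, 49 positive and 185 negative, against 2550 at an unadjusted p below 0.05. Without RT replicate 3 it called 416, with voom 702, and in the 12 samples of that time alone 94. Camera called 21 lists, 3 with an estimated correlation. The positive share, 20.9%, was 38.9% with library size as the only scaling.

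At 48 h the interaction was called for 3682 genes by edgeR, 876 positive and 2806 negative, and for 1987 without vehicle replicate 1. Cxcl10 had -4.29 ± 0.29 (adjusted p = 2.54e-12): its level was 23.5 ± 1.4 CPM with RT, 5.67 ± 0.11 with FAKi and 5.99 ± 1.3 with both. Csf2 had -3.72 ± 0.21, Ccl2 -3.47 ± 0.22, Krt6a -3.39 ± 0.18 and Mmp13 -3.09 ± 0.18. Slc16a3 and Bnip3, which lay below vehicle in all 3 treated groups, had 5.35 ± 0.18 and 5.26 ± 0.20. In the NF-kB list, 0 of 41 were positive, 32 negative and 9 did not pass (0 and 33 adjusted over the list alone), median -1.44 (camera, adjusted p = 3.07e-24). For type I interferon genes, 1 of 48 were positive, 28 negative and 19 did not pass (1 and 31 adjusted over the list alone), median -1.17 (adjusted p = 2.31e-11). For hypoxia and glycolysis, 19 of 36 were positive, 1 negative and 16 did not pass (24 and 1 adjusted over the list alone), median 0.75 (adjusted p = 8.91e-20). Camera called 27 lists, 8 with an estimated correlation. The median of all genes was -0.11. The positive share, 23.8%, was 50.2% with library size as the only scaling, 41.0% with DESeq2 and 36.2% with RLE scaling.

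Vehicle at 48 h was compared with vehicle at 24 h to show what changed in untreated cultures. Bnip3 rose by 5.21 ± 0.16 (248 ± 7.64 against 6.71 ± 0.260 CPM, adjusted p = 5.13e-21), Adm by 4.65 ± 0.20, Slc16a3 by 4.60 ± 0.14 and Ak4, a mitochondrial adenylate kinase, by 3.48 ± 0.22. Id1 and Id3, targets of BMP signalling, fell by 1.43 ± 0.18 and 1.68 ± 0.12, and Ctse, a gastric protease of classical-type tumours, by 1.61 ± 0.10. For hypoxia and glycolysis, 32 of 36 genes rose, 0 fell and 4 did not pass (32 and 1 adjusted over the list alone), median 1.34 (camera, adjusted p = 1.25e-51). For ribosomal proteins, 50 of 74 genes rose, 0 fell and 24 did not pass (73 and 0 adjusted over the list alone), median 0.81 (adjusted p = 2.7e-29, adjusted p = 0.231 with an estimated correlation). For nuclear respiratory chain subunits, 36 of 55 genes rose, 0 fell and 19 did not pass (46 and 0 adjusted over the list alone), median 0.34 (adjusted p = 4.38e-18, adjusted p = 0.119 with an estimated correlation). Library composition differed between the same groups. Mitochondrial ribosomal RNA took 0.465% to 0.478% of the counts at 48 h and 0.598% to 0.722% at 24 h, and pseudogenes 3.43% to 3.88% and 4.22% to 4.74%. By edgeR, 2416 genes changed, 1486 higher and 930 lower, and camera called 22 lists, 2 with an estimated correlation. The count was 1525 without vehicle replicate 3 at 48 h, 3798 with voom, and 4853 with only the groups compared. It was 946 with the replicate block within time, which here compares the fitted levels of replicate 1 and is less precise. The higher share, 61.5%, was 31.5% with library size as the only scaling.

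The following genes belong to a panel fixed in advance. Ptk2, which encodes FAK, passed in none of the 15 comparisons, with log2 changes from -0.25 to 0.13. Trp53 rose at 48 h with RT by 1.04 ± 0.16, with FAKi by 0.78 ± 0.16 and with both by 0.78 ± 0.16; the gene is floxed, and counts per gene do not separate its exons. Kras fell with RT+FAKi against RT at 24 h by 0.37 ± 0.10, and at 48 h fell by 0.36 ± 0.10 against FAKi and fell by 0.27 ± 0.10 against vehicle, the last of which turned to 0.14 with library size as the only scaling. Mdm2, a p53 target, rose at 48 h with RT by 0.56 ± 0.11 and with both by 0.42 ± 0.11; with RT it did not pass at 24 h (0.06 ± 0.11, adjusted p = 0.7608, edgeR). Mki67 did not pass with RT at either time and fell with FAKi by 0.54 ± 0.10 at 24 h and 0.64 ± 0.10 at 48 h. Ifnb1 was not tested, with 51 counts in all 24 libraries. H2-K1 rose with FAKi by 0.54 ± 0.09 at 24 h and 0.46 ± 0.09 at 48 h, with RT by 0.54 ± 0.09 at 48 h, and with both by 0.74 ± 0.09 at 24 h and 0.55 ± 0.09 at 48 h. Tgfb1 rose against vehicle at 48 h with RT by 1.33 ± 0.49, with FAKi by 1.34 ± 0.49 and with both by 1.33 ± 0.49, and passed in no treatment at 24 h. Krt19, a ductal keratin, rose with RT by 0.35 ± 0.08 at 24 h and 0.34 ± 0.08 at 48 h, and fell with RT+FAKi against vehicle at 48 h by 0.43 ± 0.08. Epcam rose with RT+FAKi against vehicle at 48 h by 1.29 ± 0.43, did not pass at 24 h (-0.30 ± 0.42, adjusted p = 0.6152), and varied within groups (434 ± 285 against 235 ± 57.0 CPM with FAKi at 48 h).

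Changes were compared between pairs of comparisons that share no library. FAKi against vehicle and RT+FAKi against RT at 24 h shared 1406 higher genes, against 251.7 by independence, and 2004 lower genes, against 396.7, with 17 in opposite directions; Vcam1, Acta1 and Krt4 are among the shared. At 48 h the same pair shared 1579 higher and 2373 lower, against 540.2 and 655.1, with 293 opposite. RT against vehicle and RT+FAKi against FAKi shared 498 higher and 483 lower at 24 h, against 64.9 and 69.8, with 14 opposite, and 994 higher and 1901 lower at 48 h, against 392.7 and 512.4, with 330 opposite. Between times, RT shared 1194 higher and 815 lower, against 289.5 and 184.7, with 66 opposite, and FAKi 1832 higher and 1843 lower, against 385.0 and 353.3, with 23 opposite. Across all genes, which are not independent replicates, Pearson's r was 0.398 and 0.178 for the FAKi pair, 0.278 and 0.128 for the RT pair, 0.25 for RT between times and 0.206 for FAKi between times. Among genes with an average log2 CPM of at least 3, r was in the same order 0.818, 0.716, 0.672, 0.594, 0.576 and 0.826. Expected counts by independence assume that every gene is equally likely to be called. Under the same limit, the FAKi pair shared 1043 higher and 1841 lower at 24 h, against 234.6 and 707.9. At 48 h it shared 1099 and 2144, against 345.6 and 1073. The RT pair shared 382 higher and 453 lower at 24 h, against 69.1 and 116.3. At 48 h it shared 612 and 1751, against 198.1 and 874.7. Over all genes, r of the RT pair at 48 h went from 0.128 to 0.048 without RT replicate 2 and to 0.19 without vehicle replicate 1. At 24 h it went from 0.278 to 0.175 without RT replicate 3 and to 0.298 without RT+FAKi replicate 2. For the FAKi pair at 48 h, 0.178 became 0.111 without FAKi replicate 3 and 0.232 without vehicle replicate 1. For FAKi between times, 0.206 became 0.135 without FAKi replicate 2 at 48 h and 0.236 without vehicle replicate 1 at 48 h.

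Marker lists ask whether other cell types are among the organoid cells. With RT+FAKi against RT at 48 h, 6 of 13 genes rose, 1 fell and 6 did not pass (6 and 1 adjusted over the list alone) in the fibroblast list, median 1.56 (camera, adjusted p = 0.00932, adjusted p = 0.155 with an estimated correlation). Of these Acta2, which is also an SRF target, rose by 3.28 ± 0.26 (19.3 ± 0.452 against 2.00 ± 0.568 CPM), and Col1a1 lay at 2.28 ± 0.12 against 0.842 ± 0.35 CPM. With RT at 48 h, 7 of 13 genes rose, 0 fell and 6 did not pass (7 and 2 adjusted over the list alone) in the macrophage list, median 0.40 (adjusted p = 0.0168, adjusted p = 0.0906 with an estimated correlation), among them Cd74. In the endothelial list, 4 of 11 genes rose, 0 fell and 7 did not pass (4 and 0 adjusted over the list alone) with RT+FAKi against FAKi at 48 h, median 0.79 (adjusted p = 0.0493, adjusted p = 0.246 with an estimated correlation). In the endocrine list, 1 of 10 were positive, 0 negative and 9 did not pass (0 and 0 adjusted over the list alone) for the interaction at 48 h, median 1.73 (adjusted p = 0.0417, adjusted p = 0.138 with an estimated correlation). The NOTCH, acinar, lymphocyte, neutrophil and p53 lists were called in none of the 15 comparisons. With RT+FAKi against vehicle at 48 h, their counts of genes rising and falling were 8 and 3 of 18, 2 and 0 of 17, 4 and 0 of 9, 2 and 1 of 10, and 14 and 13 of 35 (8 and 3, 1 and 0, 4 and 0, 2 and 1, 15 and 13 adjusted over the list alone).

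Positions follow the deposited files in the build GRCm38 named by the submitters. Vcam1 lies on chromosome 3 from 116110020 to 116129688, Acta1 on 8 from 123891767 to 123894736, Krt4 on 15 from 101918536 to 101924735, Krt14 on 11 from 100203162 to 100207548 and Aqp5 on 15 from 99590849 to 99594829. Cxcl10 lies on chromosome 5 from 92346638 to 92348889, Csf2 on 11 from 54247271 to 54249667, Ccl2 on 11 from 82035571 to 82037453, Cd74 on 18 from 60803848 to 60812646 and Cdkn1a on 17 from 29090979 to 29100722. Bnip3 lies on chromosome 7 from 138890836 to 138909519, Slc16a3 on 11 from 120948480 to 120960868, Cnn1 on 9 from 22099281 to 22109630 and Hist1h1b on 13 from 21779883 to 21780625.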

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

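The test of scaling for the hypoxia genes, both tests for the inflammatory genes, and the test for genomic DNA were chosen only after the result was seen; those of one vehicle library and of other splits were written before.

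Effects that differ between times were singled out by the interaction tests in edgeR. The RT effect differed for 1743 genes. Among the protein-coding ones with an average log2 CPM of at least 3, the largest positive differences were Cd74 (2.42), Lce1h (2.40), Slpi (2.35), Csf2 (2.16) and Tnf (2.10). The largest negative ones were Selenbp1 (-5.21), Bnip3 (-4.61), Slc16a3 (-4.35), Ak4 (-3.96) and Adm (-3.62). The FAKi effect differed for 569 genes. Under the same limit the largest differences were Lce1h (2.42), Cnn1 (1.99), Cd74 (1.88), Acta1 (1.84) and Wfdc18 (1.76), and Bnip3 (-4.99), Slc16a3 (-4.36), Adm (-4.31), Ak4 (-4.27) and Selenbp1 (-3.91). The effect of RT differed with FAKi from that without it for 234 genes at 24 h and 3682 at 48 h.

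Bnip3, Slc16a3 and Adm belong to the hypoxia and glycolysis list, of whose 36 genes 27 were negative for RT and 26 for FAKi, and which rose in vehicle from 24 h to 48 h with a median of 1.34. Scaling of the libraries is argued against by a median of 1.21 with library size as the only scaling, and one vehicle library by a lowest median of 1.33 with a library left out. From 24 h to 48 h the median was 0.00 in RT, 0.13 in FAKi and -0.09 in RT+FAKi, so the same time in culture did not raise the list in treated groups; for RT and FAKi this restates the differences above. Oxygen use and cell number per dome were not measured and stay open.

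Inflammatory genes were higher with FAKi, 34 of them at 48 h with a summed gain of 2240 CPM. In FAKi at 48 h, macrophages among the cells are argued against by a level of at most 0.22 CPM for Lyz2, C1qa, C1qb, C1qc, Tyrobp and Fcer1g, and fibroblasts among the cells by one of at most 1.05 CPM for Col1a1, Col1a2, Col3a1, Dcn and Lum. Cd74, of the macrophage list, lay at 20.7 CPM and Acta2, of the fibroblast list, at 6.17 CPM. Other genes that macrophages express were higher with FAKi than in vehicle at 48 h. Csf1r lay at 3.54 against 0.671 CPM, Cd68 at 7.17 against 4.71 CPM and Cd14 at 365 against 111 CPM. The argument against macrophages therefore rests on the 6 markers named first. Whether FAK itself or another target of the inhibitor is the cause stays open, since the samples hold 1 dose of 1 compound.

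Satellite-repeat loci, 6 in all including Gm10800, summed to 2420 ± 1000 CPM in RT+FAKi at 48 h against 338 ± 56.5 CPM in vehicle. Reads at 1345 olfactory and vomeronasal receptor genes were 2.1-fold higher, against 7.16-fold for the satellite loci. There were at least 24.8 satellite reads per receptor read in RT+FAKi at 48 h, against at most 17.0 in FAKi at 24 h. This would argue against genomic DNA reads as the whole cause only if every receptor read came from genomic DNA, which was not tested. If some did not, added DNA would raise the ratio too, so no conclusion on genomic DNA is drawn. Within RT+FAKi at 48 h, the library with the most satellite reads also had the most receptor reads (3492 and 107 CPM). RT replicate 3 at 24 h also had 24.8, and DNA or damaged cells stay open as a part or the whole of the cause.

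With 3 against 3 libraries there are 10 splits, too few for a share under 0.05; in each case 1 of 10, the real one, reached the real count. The real count and the highest other, at 24 h, were 3527 and 0 for RT, 5279 and 0 for FAKi and 8649 and 0 for RT+FAKi against vehicle, 5699 and 2 for RT+FAKi against RT, and 1796 and 0 against FAKi. At 48 h they were 6215 and 0, 6550 and 0, 10957 and 0, 8639 and 0, and 7119 and 0 in the same order, and 2416 and 0 for vehicle between times. Of 25 groupings of 12 samples, the real one included, 3 reached the real count for the interaction at 24 h (234, highest other 4591) and 2 at 48 h (3682, 4269). The RT effect between times was reached in 4 (1743, 2805) and the FAKi effect in 3 (569, 3584). These groupings mix libraries of different treatments or times, so the effects of treatment and time enter the contrast and can be called. The counts of other groupings therefore cannot judge the real counts, and no conclusion is drawn from them.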

How the results depend on the processing

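The tests on protein-coding genes only, and the overlap with each library left out, were chosen only after the data were seen; every alternative chosen before the data were examined was run, except that fits to 12 samples of a time do not apply between times. Of 1128 results for named genes, 960 stayed the same under every alternative, and of 20996 values 20379 did. Of the rest, 410 lost the call, 200 gained it and 7 changed sign. Same here means the same side of the threshold, and the same direction if the main fit or the alternative called the gene. Changes of sign of genes called in neither were not counted. A call without an adjusted p in DESeq2 counted as kept, and a gene not tested in an alternative was left out. Of 177 counts of changed genes 159 stayed within 1.5 times the main count, as did 91 of 114 with a library left out and 41 of 60 counts of lists. Low depth limits genes of few counts, and a floor is 0.0498 to 0.158 CPM.

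Changes of sign given here are those of results called in the main fit or the alternative. With library size only they were Kras (0.14) and Ccn2 (0.37) in RT+FAKi against vehicle at 48 h. Against FAKi at 48 h they were Top2a (0.08), Ccn2 (0.03) and Cxcl1 (0.27). With 1 surrogate variable they were Ccn2 in RT+FAKi against vehicle at 24 h (0.04) and against FAKi at 48 h (0.00). For these and the moved counts the cause was not tested.

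With 1 surrogate variable, RT at 24 h gave 1684 genes, RT+FAKi against vehicle at 24 h 4137 and against FAKi at 48 h 3952. With only the groups compared, which also leaves fewer samples, the counts were 1145 for RT at 24 h, 3274 for RT+FAKi against FAKi at 24 h, 94 for the interaction at 24 h (94 with the 12 samples of that time) and 4853 for vehicle between times. With voom they were 8601 for RT+FAKi against RT at 24 h, 3479 against FAKi at 24 h, 702 for the interaction at 24 h, 2647 and 1012 for the RT and FAKi effects between times, and 3798 for vehicle. DESeq2 gave 454 for the interaction at 24 h and 894 for the FAKi effect between times, and the stricter filter gave 380 for the interaction.

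No clear pairing by replicate number was found: 1 of 33 pairs of libraries sharing a number, in the groups compared, had a correlation over 0.1 (-0.162 to 0.122). Among libraries of other groups, 12 of 24 libraries correlated best with one of their own number. Some would do so by chance, at a level not computed, so this count leaves a weak pairing open. The replicate block within time gave 946 genes for vehicle between times. That contrast rests on the fitted levels of replicate 1 at each time and is less precise, so the lower count does not show a replicate effect. No other count moved by over 1.5 times with a replicate block.

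With a library left out the counts ran, for RT at 24 h, from 2263 (without vehicle replicate 2) to 3968. For RT+FAKi against FAKi at 24 h they ran from 1089 (without RT+FAKi replicate 1) to 1408, for the interactions from 158 to 416 (without RT replicate 3) at 24 h and from 1987 (without vehicle replicate 1) to 3550 at 48 h. For the FAKi effect between times they ran from 335 (without FAKi replicate 3 at 24 h) to 688, and for vehicle from 1525 (without replicate 3 at 48 h) to 2235.

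Lists called with an estimated correlation came to 6 from 22 (RT), 12 from 29 (FAKi), 15 from 26 (RT+FAKi against vehicle), 14 from 28 (against RT), 3 from 14 (against FAKi) and 3 from 21 (interaction) at 24 h. At 48 h they were 14 from 31 (RT), 18 from 29, 9 from 23, 5 from 11 and 8 from 27 (RT+FAKi and interaction, same order), and between times 9 from 20 (RT), 5 from 20 (FAKi) and 2 from 22 (vehicle). Fry gave 41 (RT+FAKi against vehicle, 24 h), 12 (interaction, 24 h), 40 (against RT, 48 h) and 33 (against FAKi, 48 h), and library size 18 (against FAKi, 48 h).

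Among genes with an average log2 CPM of at least 3, Pearson's r was 0.818 and 0.716 (24 h, 48 h) for FAKi with and without RT, 0.672 and 0.594 for RT with and without FAKi, and 0.576 and 0.826 between times for RT and FAKi. With a library left out, in that order, r over all genes ran from 0.338 to 0.413, 0.111 to 0.232, 0.175 to 0.298, 0.048 to 0.19, 0.186 to 0.297 and 0.135 to 0.236.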

Other observations

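The prediction for the list of FOXO targets was written before the list was tested, but the list was drawn up after the main results. Those results already held the changes of single members with FAKi, and Bcl2l11 was among the genes picked there. The test is therefore not independent of values already at hand.

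FOXO factors are held in the cytoplasm by AKT, which FAK can activate, so a hypothesis was that FOXO target genes rise with FAKi. Of 20 targets, 13 rose, 0 fell and 7 did not pass at 24 h (median 0.65; camera adjusted p = 3.28e-08, and 0.0184 with an estimated correlation). At 48 h, 11 rose, 1 fell and 8 did not pass (median 0.72; adjusted p = 9.53e-07, and 0.0206 with an estimated correlation). Fbxo32, a ubiquitin ligase, rose by 2.11 and 2.91 at 24 h and 48 h, Txnip, which limits glucose uptake, by 1.12 and 1.70, Bcl2l11, a killer of the BCL2 family, by 1.17 and 1.40, and Pik3ip1, a brake on PI3 kinase, by 0.66 and 1.93. The list was tested for FAKi against vehicle only, so its response to RT was not examined. Bcl2l11 lay at 15.3 CPM in vehicle, 20.7 with RT and 34.2 with FAKi at 24 h. At 48 h it lay at 14.4, 34.5 and 38 CPM in the same order. With FAKi, Ccng2 rose by 0.58 at 24 h and fell by 0.40 at 48 h, while Cdkn1b and Sesn1 passed at neither time. The lists hold no measure of where FOXO proteins lie, so another regulator of these genes stays open.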
